A study of Rattus norvegicus with 10 samples.

How the data were processed

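RNA was extracted with Trizol from flash-frozen lungs and made into Illumina libraries with the NEBNext Ultra kit from total RNA, per the labels' protocols. The kit name as given does not state that strand was kept, so reads of overlapping and antisense genes may be counted together. Reads were aligned with HISAT2 2.0.5 and counted with featureCounts 1.5.0-p3, per the submitters' processing notes. The genome build, the annotation release and the tool behind the authors' fold changes and p-values are not given in the sources used here. Coordinates are therefore printed as the authors' table gives them, without a build.

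A single table was used. It held 1319 genes, each with a p-value under 0.05 from the authors (highest 0.04998), and its columns were understood from the file headers and the values. The 10 library columns hold a signal, the authors' read counts per gene divided by 1 size factor per library, called scaled counts here. Every value of a library was a whole multiple of what 1 read is worth in it, within a tolerance of 0.02 reads, for 100% of values. One read was worth between 0.869 and 1.11 scaled counts. The deposited table also gives the authors' group means of this signal, a log2 fold change, a fold (ratio) and unadjusted and adjusted p-values for each gene, and other columns per the file headers such as gene length, which was not used in any test. The authors' adjusted p-values match a Benjamini-Hochberg adjustment over 19894 genes, except at 6 listed genes whose values it cannot give. The listed genes are therefore about 6.63% of those adjusted, and numbers that rest on the 19894 genes are approximate. The table gives a symbol, a description and an identifier for most genes, and 127 genes had no symbol. Another 7 symbols were written as calendar dates and were left as they were, and 1 symbol was shared by 2 genes, which were kept apart by identifier. Depth per library cannot be had from a table of selected genes, and the reads in listed genes are given in place of it.

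Libraries were put in groups by their genotype label, 5 WT and 5 Cmg2-KO, and every library column was matched to its label. The series text speaks of more libraries per genotype than the 5 analysed here. The comparison, the alternatives, the rule for named genes and 59 gene lists were fixed before the data were examined. The plan assumed a count table of all genes with edgeR's quasi-likelihood test. Since the table held scaled counts of selected genes, the test planned for normalized values was used in its place. This was limma 3.58.1 (trend and robust options) in R 4.3.3 on log2(scaled count + 1), over the 1308 genes with a value above 0.5 in at least 5 libraries. Benjamini-Hochberg adjustment used all 19894 genes, the genes outside the table counting as not passing. Log2 fold changes are Cmg2-KO over WT on the log2(scaled count + 1) scale, which understates the change of low genes. The moderated variances were estimated from genes selected for this contrast.

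The rule for named genes took Antxr2 and Antxr1, then the 10 genes with the largest log2 fold change in each direction among those past the threshold. Such genes needed a symbol other than a LOC, RGD, AABR, AC or Ensembl-style name, a mean of at least 1 in the higher group, and at least 4 of 5 libraries of one genotype beyond all 5 of the other. It also took up to 4 members of each list past its threshold. Antxr2 and Antxr1 were not analysed here, and no gene past limma's threshold had such a symbol. The same rule was therefore applied with the adjusted p-value of the authors' deposited table, a choice made after the values were seen. A further 2 list members counted in the tests are not reported by name here. Loxl1, Siglec5 and the list members given as examples were also chosen after their values were seen.

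Each list was tested in 3 ways. Camera with a preset correlation of 0.01 was run on lists with at least 4 listed members (12 lists), with an estimated correlation and fry beside it. Over-representation among the listed genes was tested with a one-sided Fisher's exact (hypergeometric) test on 57 lists, taking every symbol of a list as one of the 19894 genes, and the share of lower members with a two-sided Fisher's exact test. Counts adjusted over the list alone used every gene of a list, those outside the table counting as not passing, a choice made after the values were seen. The tests of over-representation and of direction were added after the table was seen. Camera and fry ran within genes already selected for the contrast, so their p-values are not those of a whole transcriptome.

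Alternatives to the main settings covered library scaling, filters, pseudocount, test, adjustment, replicate block, surrogate variables (sva 3.50.0) and leaving out each library. Count tests with edgeR 4.0.16, DESeq2 1.42.0 and limma-voom used the recovered whole reads of 9 libraries with the authors' size factors. WT 4 stayed out because 1 of its reads is worth 1.01 scaled counts, which the recovery rule treated as too close to 1. Its values were whole multiples of that step, as in the other libraries. The count tests therefore differ from limma by a lost library as well as by the method. The limma procedure was tested on simulated counts for 19894 genes in this comparison. With no gene changed it called 0. With 200 genes changed 2-fold it called 146, of which 8 were false, and recovered 69% of the changed genes. With 200 genes changed 1.5-fold it called 103, of which 6 were false, and recovered 48.5%. The changed genes were drawn only from those with higher means. Simulated means and spreads came from genes selected for this contrast, and the genes were simulated as independent. The shares recovered therefore do not apply to genes of few reads and may not hold for these data. Permutations and shuffles were run in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, with fixed seeds.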

Results

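Gene expression was measured by RNA sequencing in lung of 8-week-old Sprague Dawley rats, an outbred laboratory strain. The libraries fell into 2 groups by genotype, 5 from wild-type (WT) rats and 5 from rats lacking Cmg2, the gene for capillary morphogenesis gene 2 protein. That protein, also called ANTXR2, is a transmembrane receptor for anthrax toxin that binds matrix proteins such as collagen IV and laminin. The values analysed were read counts scaled by the authors, for the 1319 genes whose unadjusted p-value in the authors' deposited table was under 0.05. The scaled counts of these genes summed to between 1386578 and 1531531 per library, and the whole reads behind them to between 1289524 and 1620198 in the 9 libraries where reads were recovered. The total depth of the libraries is unknown. Nothing in the labels says whether the libraries of a group came from separate animals, so the p-values measure the spread among these libraries. The targeted gene, Antxr2, and its relative Antxr1 were not analysed here, so the genotype labels have no check from the targeted transcript.

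The single comparison, Cmg2-KO against WT, asked how the lung transcriptome differed when Cmg2 was missing. A small set of genes differed strongly. A gene model on chromosome 5 described as a probable rRNA-processing protein rose 20.5-fold in Cmg2-KO lung, and a pair of adjoining unnamed models on chromosome 16 fell to under 4 scaled counts in every Cmg2-KO library. Below these, Galnt16, Clec2dl1, Faah and Klrc2 were higher and Gpr27, RT1-M6-2 and Gstt3 lower in all 5 Cmg2-KO libraries than in any WT library. None of these passed limma's adjusted threshold, while all passed in the authors' deposited table. Among functional groups, all 10 listed smooth muscle genes and all 7 listed circadian clock genes were lower in Cmg2-KO, and all 6 listed mesothelial genes were higher, by median log2 fold changes of -0.48, -0.87 and 0.63. These medians cover only members already selected for this contrast, and no list passed the adjusted threshold of the planned camera test.

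LOC108348080 (chromosome 5, 137670123 to 137674802, plus strand), the probable rRNA-processing gene model, rose from 9.35 ± 6.64 to 215 ± 135 scaled counts (SD, n = 5 per genotype), a log2 fold change of 4.36 ± 0.48 (SE; limma, adjusted p = 0.0175). The unnamed model at 19247067 to 19247942 on the minus strand of chromosome 16 fell from 79.4 ± 36.2 to 0.936 ± 0.672 scaled counts, with a log2 fold change of -5.29 ± 0.44 (SE; limma, adjusted p = 0.00289). Its neighbour at 19243896 to 19246637 on the same strand fell from 125 ± 76.4 to 1.5 ± 1.3 scaled counts, with a log2 fold change of -5.54 ± 0.57 (SE; limma, adjusted p = 0.0112). All 5 libraries of one genotype lay beyond all 5 of the other at each of these models. They were the only 3 of the 1308 genes tested that passed limma's adjusted threshold of 0.05, with 1 higher and 2 lower, while 1035 genes had an unadjusted limma p under 0.05. The authors' deposited table gave an adjusted p under 0.05 to 72 genes, 41 higher and 31 lower in Cmg2-KO, and these included the 3 passed by limma. Of the 72 genes in the authors' deposited table, 14 had no symbol and a further 14 had provisional names starting with AABR, LOC, RGD or AC.

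The genes described next had a symbol other than these, an adjusted p under 0.05 in the authors' deposited table, and no limma adjusted p under 0.05. Galnt16 (chromosome 6, 104068547 to 104250174), an enzyme that starts mucin-type O-glycosylation, stood at 32.3 ± 15.7 scaled counts in WT and 139 ± 20.5 in Cmg2-KO (SD, n = 5). Its adjusted p was 2.8e-09 in the authors' deposited table and 0.111 in limma. Genes described as killer cell, C-type lectin or leukocyte immunoglobulin-like receptors went both ways among the listed genes, with 8 higher and 5 lower (two-sided Fisher's exact test against the other listed genes, p = 0.409, adjusted p = 0.678 over 12 keyword groups chosen after the values were seen). Clec2dl1, a C-type lectin gene on chromosome 4 (162281574 to 162402635), stood at 16.0 ± 6.45 in WT and 79.6 ± 25.6 in Cmg2-KO, a log2 fold change of 2.26 ± 0.31 (SE; limma, adjusted p = 0.073). Klrc2, a killer cell lectin-like receptor gene in the same chromosomal region (163416351 to 163445302), had a log2 fold change of 1.04 ± 0.25 (SE). Micb stood at 171 ± 14.9 and 398 ± 142, with 4 Cmg2-KO libraries between 430 and 492 and the fifth, Cmg2-KO 4, at 147. Lilrb3, an inhibitory leukocyte immunoglobulin-like receptor gene, stood at 5.05 ± 1.73 and 22.5 ± 11.3, and Cmg2-KO 4 was again at WT level with 4.73. Siglec5, another leukocyte receptor gene, was lower, at 533 ± 115 in WT and 339 ± 54.6 in Cmg2-KO, with an adjusted p of 0.0358 in the authors' deposited table. Reads from the families of these genes can be shared between close copies, so their levels are uncertain.

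Faah, which encodes the hydrolase that breaks down the endocannabinoid anandamide, stood at 7.82 ± 11.3 scaled counts in WT and 74.0 ± 20.5 in Cmg2-KO (SD, n = 5), a log2 fold change of 3.80 ± 0.64 (SE; limma, adjusted p = 0.183). It lies on chromosome 5 at 134331929 to 134348995, within 4 Mb of LOC108348080. Chrnb3, a nicotinic acetylcholine receptor subunit, stood at 3.59 ± 2.17 and 19.7 ± 11.7. Vash1, encoding vasohibin-1, an endothelial inhibitor of angiogenesis, stood at 215 ± 25.3 and 339 ± 63.2 and was higher in all 5 Cmg2-KO libraries than in any WT library. The X-linked genes Armcx6 and Smarca1, the latter encoding an ATPase of chromatin remodelling complexes, had log2 fold changes of 0.66 ± 0.15 and 0.61 ± 0.14 (SE). Loxl1, a lysyl oxidase that cross-links elastin and collagen, was at 2319 ± 420 in WT and 3353 ± 164 in Cmg2-KO, with an adjusted p of 0.00653 in the authors' deposited table.

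Among the lower genes, Gstt3 (chromosome 20, 13817795 to 13825475), a theta-class glutathione S-transferase, had the most reads. It stood at 790 ± 266 scaled counts in WT and 338 ± 42.6 in Cmg2-KO (SD, n = 5), a log2 fold change of -1.16 ± 0.22 (SE; limma, adjusted p = 0.282), with an adjusted p of 2.45e-05 in the authors' deposited table. RT1-M6-2, a class Ib major histocompatibility gene on the same chromosome (2076267 to 2081885), stood at 73.3 ± 26.2 and 19.3 ± 6.50. Gpr27, an orphan G protein-coupled receptor gene, stood at 26.7 ± 14.4 and 3.79 ± 1.16, and Rfx4, a transcription factor gene, at 17.3 ± 8.28 and 2.83 ± 1.81. Zp2, an egg-coat glycoprotein gene, stood at 30.0 ± 7.40 and 9.37 ± 6.59, Fam83c at 51.8 ± 7.14 and 21.4 ± 9.50, and Mfsd14a at 51.4 ± 38.2 and 14.3 ± 2.63. Trim54, a muscle RING-finger gene, had a log2 fold change of -1.09 ± 0.28 (SE), with WT 2 at 116 and the other WT libraries between 53.6 and 65.5. Mis18a, which is needed to load the centromeric histone, ranged from 6.66 in WT 3 to 123 in WT 4 and from 3.51 to 20.9 in Cmg2-KO. NEWGENE_1310561, a placeholder name, ranged widely in WT, from 6.66 in WT 3 to 478 in WT 1, against 4.73 to 11.5 in Cmg2-KO.

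**Figure D1:**
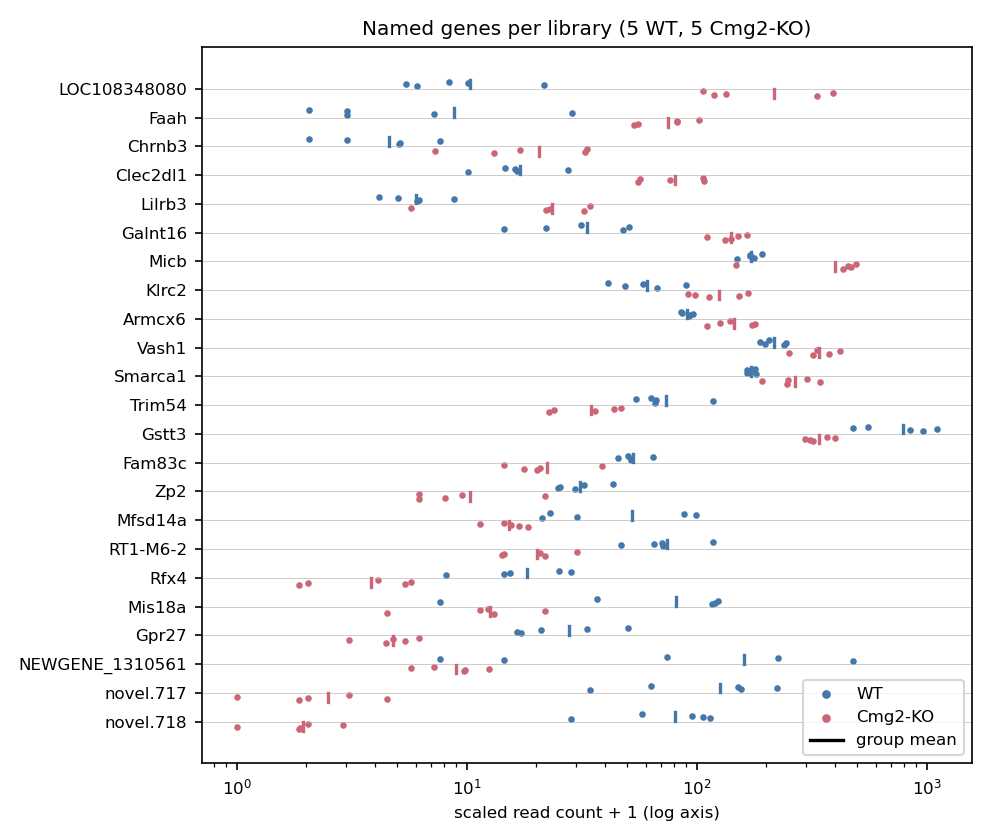
Scaled read count plus 1 (log axis) of each named gene and of the 3 genes past limma's threshold in each library, with 5 WT libraries in blue, 5 Cmg2-KO libraries in red and vertical bars at the group means. The chromosome 16 models at the bottom have Cmg2-KO libraries near 0 counts, and Cmg2-KO 4 lies just below the WT libraries for Micb and among them for Lilrb3.

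The listed genes of smooth muscle and its contractile apparatus were lower in Cmg2-KO lung. Of 17 genes on this list, 10 were among the listed genes where 1.13 would be by chance, and all 10 were lower (one-sided Fisher's exact test for over-representation, adjusted p = 1.15e-06 over 57 lists). Myosin heavy chain Myh11 averaged 10577 ± 2112 scaled counts in WT and 7375 ± 1517 in Cmg2-KO (SD, n = 5), and the actin-binding protein gene Tagln 11540.4 ± 1663 and 8769 ± 1724. Tropomyosin Tpm2 had a log2 fold change of -0.61 ± 0.18 and myosin light chain Myl9 of -0.48 ± 0.12 (SE). None passed over all genes in limma or in the authors' deposited table, and 4 passed, all lower, adjusted over the list alone (17 genes). Lower genes were a larger share of this list than of the other listed genes (Fisher's exact test, adjusted p = 0.024 over 12 lists). With camera, which compares the list with the other listed genes, the adjusted p was 0.0729, and the adjusted p = 0.489 with an estimated correlation. The members varied together within the genotypes, with a mean residual correlation of 0.664 across the libraries, so the p-values for over-representation and for the share of lower genes are too small.

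The listed mesothelial genes, which mark the pleural lining, were higher in Cmg2-KO. Of 10 on the list, 6 were listed (0.663 by chance), all higher (one-sided Fisher's exact test, adjusted p = 0.000399), and 0 passed adjusted over the list alone (10 genes) or over all genes in limma. Mesothelin (Msln) averaged 1482 ± 362 scaled counts in WT and 2332 ± 648 in Cmg2-KO (SD, n = 5), the uroplakin gene Upk3b 569 ± 111 and 882 ± 179, while Lrrn4 had a log2 fold change of 0.85 ± 0.29 (SE). The test of the share of lower genes against the other listed genes did not pass (Fisher's exact test, adjusted p = 0.0632). In Cmg2-KO 1, Upk3b at 574 and the transcription factor gene Wt1 at 77.3 lay at WT level. The members had a mean residual correlation of 0.722 across the libraries, so both Fisher p-values are too small. The camera adjusted p was 0.0764, and the adjusted p = 0.489 with an estimated correlation.

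The listed core clock and clock-output genes were lower in Cmg2-KO. Of 21 on the list, 7 were listed (1.39 by chance), all lower (one-sided Fisher's exact test, adjusted p = 0.00536), and 0 passed adjusted over the list alone (21 genes) or over all genes in limma. The period genes Per2 and Per3 averaged 1023 ± 725 and 1075 ± 622 scaled counts in WT and 482 ± 111 and 541 ± 255 in Cmg2-KO (SD, n = 5). Log2 fold changes were -0.87 ± 0.31 for the output transcription factor Hlf, -0.75 ± 0.20 for Usp2 and -0.31 ± 0.15 for the repressor Cry2 (SE). The test of the share of lower genes gave an adjusted p of 0.0632 (Fisher's exact test), and the members had a mean residual correlation of 0.628, so both Fisher p-values are too small here as well. The spread among WT libraries was wide, with an SD of 0.60 in the mean log2 value of the 7 genes against 0.21 in Cmg2-KO. The camera adjusted p was 0.0764, and the adjusted p = 0.489 with an estimated correlation. Without WT 5 the median log2 fold change of the 7 genes was -0.55.

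Genes for fibrillar collagens, their processing and elastic fibres were higher where they were listed, in numbers that did not pass the test of over-representation. Of 24 collagen and processing genes, 5 were listed and all were higher (1.59 by chance; one-sided Fisher's exact test, adjusted p = 0.163), and 1, Loxl1, passed adjusted over the list alone (24 genes). The 5 were Loxl1, Col16a1, Col11a1, the prolyl hydroxylase gene P4ha3 and the procollagen C-proteinase enhancer gene Pcolce. The test of direction gave this list an adjusted p of 0.0776 (Fisher's exact test). Camera gave it an adjusted p of 0.0764, and an adjusted p = 0.489 with an estimated correlation. Elastin (Eln) averaged 8746 ± 2672 scaled counts in WT and 14704 ± 5929 in Cmg2-KO (SD, n = 5), and was 1 of 3 elastic fibre genes of 17 listed, with Emilin1 and Ltbp1, all higher (1.13 by chance; one-sided Fisher's exact test, adjusted p = 0.375). None of the 5 collagen VI genes was among the listed genes analysed here.

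Secretory airway and xenobiotic-metabolising genes were lower where listed, again without passing the test of over-representation. For the secretory airway list these were 4 of 17 genes, Scgb1a1, Cyp2f4, Agr2 and Bpifb1 (1.13 by chance; one-sided Fisher's exact test, adjusted p = 0.163; camera adjusted p = 0.159). Scgb1a1, which encodes the club cell secretory protein, had the most reads of them. It stood at 157447 ± 21396 scaled counts in WT and 116928 ± 35493 in Cmg2-KO (SD, n = 5). Quantile normalization left it with a log2 fold change of 0. A gene that keeps its rank in every library gets the same value from that method, so this 0 does not test the decrease. Cyp2f4 averaged 758 ± 330 and 326 ± 302. For the xenobiotic list they were 5 of 18 genes, among them Ephx1, Cyp1b1, Cyp2e1 and Fmo2 (1.19 by chance; one-sided Fisher's exact test, adjusted p = 0.075; camera adjusted p = 0.14). The flavin monooxygenase Fmo2, an abundant lung enzyme, averaged 13296 ± 5059 in WT and 9308 ± 2021 in Cmg2-KO. WT 5 was at 22150, while the other WT libraries, at 9315 to 12034, overlapped Cmg2-KO at 6240 to 11368.

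**Figure D2:**
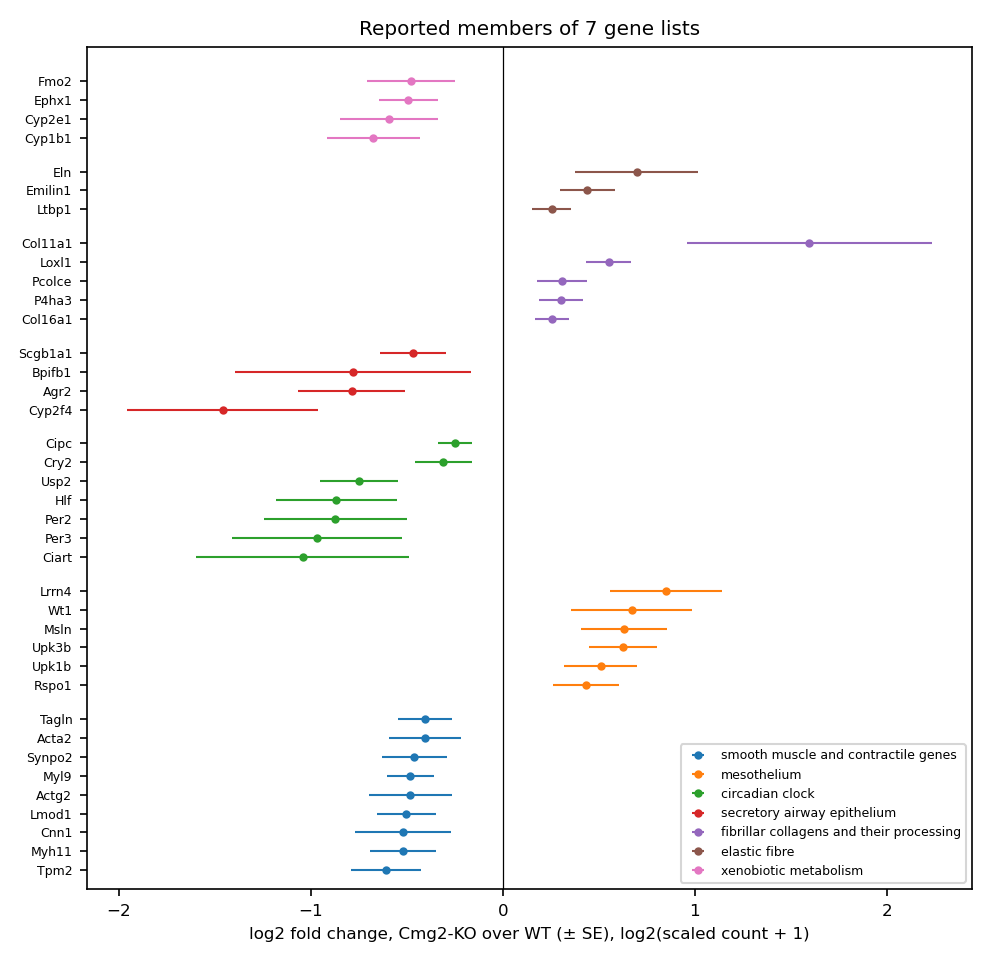
Log2 fold change of Cmg2-KO over WT on log2(scaled count + 1), as points with SE bars, for the members of 7 gene lists reported here (5 libraries per genotype; colours mark the lists). Smooth muscle, clock, secretory airway and xenobiotic members lie below 0, and mesothelial, collagen and elastic fibre members above 0. Under quantile normalization Scgb1a1 moved to 0, the value which that method gives a gene of unchanged rank.

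**Figure D3:**
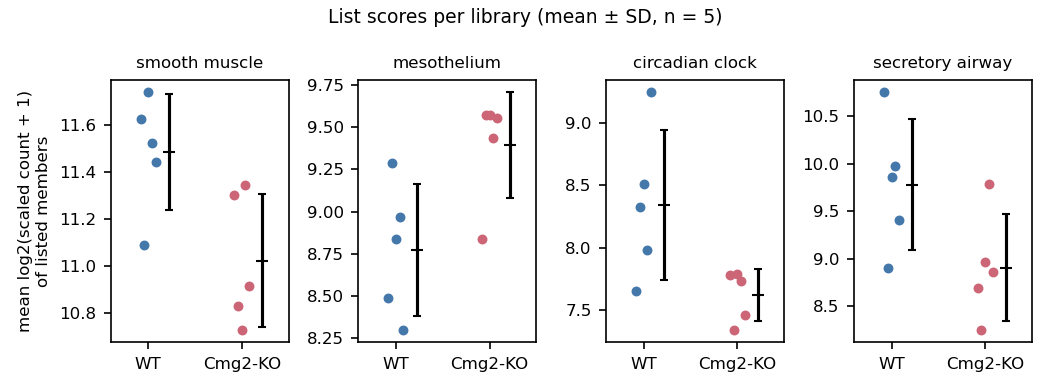
Mean log2(scaled count + 1) of the listed members of 4 gene lists in each library (points), with the group mean and SD (n = 5) as horizontal and vertical black bars; each panel has its own vertical axis, which does not start at 0. The genotypes overlap in every panel. Below all WT libraries lie 3 Cmg2-KO libraries for smooth muscle, 2 for the clock and 3 for secretory airway, and 4 lie above them for mesothelium.

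Other cell types were represented by few listed genes. Lists for neutrophils, natural killer cells, erythroid cells, alveolar type 1 epithelium, thymus, cardiac muscle, skeletal muscle and cytosolic ribosomal proteins had 0 members among the listed genes. B and plasma cell genes had 3 of 19, all higher, including the immunoglobulin J chain gene Jchain at 3016 ± 939 and 4700.3 ± 1084 scaled counts (SD, n = 5). Pericyte genes had 2 of 12, Lamc3 and Rgs5, both lower like smooth muscle, with log2 fold changes of -0.50 ± 0.15 and -0.46 ± 0.17 (SE; over-representation adjusted p = 0.592, one-sided Fisher's exact test). Fibroblast genes had 2 of 20, Dcn and Pi16, also both lower, at -0.84 ± 0.28 and -0.60 ± 0.25 (SE; over-representation adjusted p = 0.816, one-sided Fisher's exact test). Capillary genes had 2 of 13 and shared endothelial genes 1 of 17. The list of VEGF and angiogenesis signalling had 5 of 21, with Flt4, Vegfc, Dll4 and Apln higher and Tie1 lower (1.39 by chance; one-sided Fisher's exact test, adjusted p = 0.121). Hypoxia and glycolysis genes had 5 of 25, all lower, and unfolded protein response genes 4 of 24, all higher, with over-representation adjusted p-values of 0.163 and 0.367 by one-sided Fisher's exact test. Matrix proteoglycans went both ways, with decorin (Dcn) at 2196 ± 988 and 1159 ± 293 and fibromodulin (Fmod) at 1905 ± 272 and 2722 ± 628. No list of 12 tested passed an adjusted camera p of 0.05, and 4 had an unadjusted camera p under 0.05. The rotation test fry, which asks whether a list moved one way on balance, passed 8 of the 12, on genes already selected for the same contrast.

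The number of listed genes limits what these tests show. At a p-value under 0.05, 994.7 of the 19894 genes in the authors' adjustment would be listed by chance, against 1319 listed, so much of the list is compatible with no change.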

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

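The genes examined in this part were chosen after their values were seen, and the criterion applied to them was fixed beforehand. In each genotype, a library was picked out when its log2 value lay apart from the other 4 by more than 0.71 of the group's range (Dixon's criterion). This was applied to 61 genes, the named genes and the reported members of 7 gene lists, and picked out 8 of 122 groups of 5 libraries, where chance at 1 in 20 gives about 6.1.

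Cmg2-KO 4 had 4.73 scaled counts of the leukocyte receptor gene Lilrb3 against 21.1 to 33.3 in the other Cmg2-KO libraries. The same library had 147 scaled counts of Micb against 430 to 492. Both values lie in or next to the WT range. WT 2 had 116 scaled counts of the muscle gene Trim54 against 53.6 to 65.5 in the other WT libraries.

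Of the mesothelial genes, Cmg2-KO 1 had 574 scaled counts of Upk3b against 907 to 1029 in the other Cmg2-KO libraries, and 77.3 of Wt1 against 119 to 140. WT 1 had 195238 scaled counts of Scgb1a1, the club cell secretory protein gene, against 143906 to 152709 in the other WT libraries. WT 5 had 1211 scaled counts of the collagen-processing gene Pcolce, above the 721 to 820 of the other WT libraries, and 1212 of the elastic fibre gene Emilin1, below their 1791 to 2035. No library had more than 2 of the 8 values.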

How the results depend on the processing

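Chosen after seeing the data were the edgeR test on 9 libraries and the limit of the planned DESeq2 and limma-voom tests to those libraries, the scaling to a common total, the filter at 10 scaled counts, the adjustment over listed genes alone, the authors' adjusted p-value, and the list tests of over-representation and direction. Each named gene kept its direction under each alternative that gave it a value. Of the listed genes, 8 changed sign or moved to 0 under quantile normalization, of which Scgb1a1, at 0, belongs to the lists described, and 0 changed sign under the common total. List members were otherwise not run one by one. The 3 genes of limma became 5 with quantile normalization, 49 with DESeq2 on 9 libraries, 256 adjusted over the listed genes only and 72 by the authors' deposited table, and all 3 were among the genes called in each of these. They became 1 with edgeR on 9 libraries, 1 at an adjusted p under 0.01, and 0 with limma-voom on 9 libraries and 0 with 2 surrogate variables, where 722, 742 and 390 genes had an unadjusted p under 0.05 with edgeR, limma-voom and surrogate variables. Fewer genes in the adjustment explain the 256. For the rest the cause was not tested. The tests on 9 libraries also lack WT 4, without which limma itself gave 1 gene. Leaving out 1 library gave 1 to 6 genes, with 1 without WT 4 and without Cmg2-KO 1, 2 without WT 1, 5 without WT 3, and 6 without Cmg2-KO 3 and without Cmg2-KO 4. LOC108348080 lost its call without WT 1, WT 4, WT 5 or Cmg2-KO 1 (limma, adjusted p = 0.0783, 0.0759, 0.0506 and 0.0701). The chromosome 16 model at 19243896 lost its call without WT 4 or Cmg2-KO 1 and with a pseudocount of 0.1 (limma, adjusted p = 0.0678, 0.0664 and 0.0762). Micb passed without Cmg2-KO 4 (limma, adjusted p = 0.000651), Faah and Clec2dl1 without WT 3 (limma, adjusted p = 0.01 and 0.0389), and Clec2dl1 with quantile normalization (limma, adjusted p = 0.0487). Galnt16, Gstt3, Clec2dl1, RT1-M6-2, Gpr27, NEWGENE_1310561, Faah and Micb passed with DESeq2 on 9 libraries (DESeq2, adjusted p from 8.9e-10 for Galnt16 to 0.0494 for Micb). None of them passed with edgeR or limma-voom on the same libraries. The other filters and the common total gave 3 genes and a pseudocount of 0.1 gave 2.

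With the replicate number as a replicate block, 0 genes passed (899 at an unadjusted limma p under 0.05) and 3 lists did, smooth muscle, mesothelium and fibrillar collagens. The numbers were not taken to pair the libraries, since no same-numbered residual correlation was above 0.1 (0.0789, 0.0873, -0.0156, 0.0698 and 0.0218). A weak pairing stays open, as 5 libraries of 10 correlated best with their own number where 2 would by chance.

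The count of lists past camera's threshold was 0, and became 1 with quantile normalization (smooth muscle), 8 with fry, 3 by over-representation and 1 by direction; the cause was not tested. It stayed at 0 with an estimated correlation (none of the 4 lists with an unadjusted p under 0.05 held) and with surrogate variables. Leaving out 1 library gave 0 to 2 lists, with smooth muscle and mesothelium passing without WT 2 and without Cmg2-KO 1, and smooth muscle without Cmg2-KO 4. Of the values of single genes under alternatives, 430 kept their side of the threshold, 30 moved past it (18 by adjusting over the listed genes only, 8 with DESeq2) and 18 fell short of it, and for lists 163 kept it and 17 moved past it. Not run were a sex covariate, since no gene of the fixed sex-linked list was among those analysed, and scaling by median ratios, raw totals and a CPM filter, which need counts of all genes. Antxr2 has no value under any setting. Depth limits genes of a few reads, such as the chromosome 16 models in Cmg2-KO.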

Other observations

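The tests of neighbouring genes and of library scaling, the description keywords and the chromosome 6 region were chosen after the result was seen.

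The listed genes described as parts of cilia or axonemes were lower in Cmg2-KO without passing an adjusted test, a group that the fixed list of ciliated cells met with 1 gene of 24. A search of the gene descriptions found 8 such genes, all lower, with a median log2 fold change of -0.52 (two-sided Fisher's exact test against the other listed genes, p = 0.00792, adjusted p = 0.0951 over 12 keyword groups tried). The axonemal dynein genes Dnah7, Dnai2 and Dnah17 averaged 247 ± 81.3, 200 ± 65.8 and 49.2 ± 9.42 scaled counts in WT and 165 ± 44.7, 135 ± 34.3 and 34.1 ± 5.42 in Cmg2-KO (SD, n = 5). The dynein assembly factor gene Dnaaf1 had a log2 fold change of -0.58 ± 0.23 (SE). All 6 listed regulators of G-protein signalling were also lower, Rgs2, Rgs4, Rgs5, Rgs16, Rgs17 and Rgs20 (median log2 fold change -0.78, two-sided Fisher's exact test, p = 0.0315, adjusted p = 0.189). Rgs17 and Rgs20 had few reads, averaging 4.33 and 3.51 scaled counts in WT. In WT 5, Rgs4 was at 518 against 159 to 217 in the other WT libraries, and Rgs2 at 1299 against 529 to 938. Rgs16 averaged 144 ± 63.4 in WT and 68.4 ± 18.7 in Cmg2-KO, and Rgs5, a pericyte marker, 727 ± 192 and 520 ± 77.1. Neither group passed its adjusted threshold.

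Some of the genes called in the authors' deposited table were set by part of a group. Ndufa1, a respiratory chain subunit gene, had 389 and 698 scaled counts in Cmg2-KO 4 and Cmg2-KO 5 and between 6.07 and 14.6 in the other 8 libraries. An unnamed model on chromosome 5 at 98932065 to 98933404 had 102 to 158 scaled counts in 4 Cmg2-KO libraries, 0 in Cmg2-KO 3 and 0 to 4.44 in WT. Another at 95659761 to 95663859 had 154 to 212 in the same 4 Cmg2-KO libraries, 6.27 in Cmg2-KO 3 and 2.02 to 20.7 in WT. Mark3, a kinase gene on chromosome 6, had 1277 in Cmg2-KO 4, in the WT range of 1183 to 1343, against 1940 to 2343 in the other Cmg2-KO libraries. On chromosome 6 from 136041777 to 146395025, the span of the largest cluster of genes called in the authors' deposited table, 14 listed models with names starting with AABR included 10 higher and 4 lower, and AABR07065883.1 there reached 1913 scaled counts in Cmg2-KO 2 alone.

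The 72 genes called in the authors' deposited table lay near one another. They formed 28 pairs within 5 Mb, against a mean of 14.8 when the calls were shuffled among listed genes (10000 shuffles, permutation p = 0.0085), and 12 clusters held 32 of them, such as Faah with LOC108348080 and Clec2dl1 with Klrc2. Merging genes within 0.2 Mb left 22 pairs against 10.8 shuffled (permutation p = 0.0046), so models that close did not make the excess. Models of 1 locus that lie farther apart stay separate in this count, which cannot exclude them. Without chromosome 6, which holds the largest cluster, 13 pairs were left against 8.02 after merging (permutation p = 0.0713), and of 11 genes fixed as neighbours of Antxr2 only Cxcl13 was listed (0.729 by chance; one-sided Fisher's exact test, p = 0.53). Linked sequence differences between the rats of the 2 groups, in an outbred strain, could give such clustering. The shuffles ignore that neighbouring genes may vary together for other reasons, so the excess cannot single out linked differences. An effect of Cmg2 on several genes of one region also stays open and untested.

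The 7 clock genes were lower together, and their median log2 fold change was at most -0.55 (-0.552) when any 1 library was left out. They had been selected for this contrast with all libraries, so this cannot exclude that 1 library made much of the pattern. Only 2 Cmg2-KO libraries had a mean log2 value of the 7 genes below all WT libraries. The genes also varied together within the genotypes, with a mean residual correlation of 0.628 where 95% of 10000 random sets of 7 listed genes gave less than 0.166. This is consistent with a difference in the hour of tissue collection among rats, as is the wide WT spread. Such a correlation would also follow from any other input shared by clock genes. An effect of genotype on the clock stays open, since collection times are not given in the labels.

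The listed smooth muscle and airway genes were lower while the listed mesothelial genes were higher, and the airway list passed no adjusted test of its own. Library scaling would move the lists alike and cannot part them, and the smooth muscle median lay below the mesothelial one by a log2 difference of -1.11 (-1.109; range -1.35 to -0.96 when 1 library was left out). The members had been selected for this contrast with all libraries. Selection may thus have enlarged this difference, and its range is no separate support. If parts of lungs rather than whole lungs were used, sampling of a more peripheral part in Cmg2-KO could give this pattern. Such sampling cannot be told apart from an effect of genotype, because a difference in sampling between the groups would coincide with the genotype. Within genotypes the mesothelial score against the mean smooth muscle and airway score gave r = -0.387 (exact permutation within groups, one-sided p = 0.144, two-sided p = 0.305, adjusted p = 0.407 over 4 relations) and rho = -0.44 (exact p = 0.243). Without the 2 libraries farthest from the median mesothelial score r was -0.84. Of the other relations, mesothelium against smooth muscle gave r = -0.59 (exact permutation, two-sided p = 0.0919, adjusted p = 0.184) and rho = -0.68 (p = 0.0334), with r = -0.70 without the 2 farthest. Mesothelium against airway gave r = -0.26 (exact permutation, two-sided p = 0.501, adjusted p = 0.501), and r = -0.84 without the 2 farthest. Smooth muscle against airway gave r = 0.65 (exact permutation, two-sided p = 0.0593, adjusted p = 0.184), and r = 0.34 without the 2 libraries farthest from the median smooth muscle score.

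Other splits of the libraries give no test of the 3 genes called by limma. Of 100 splits of the 10 libraries into 5 and 5, drawn with the real one included, the real one gave 3 genes and the highest other split 1, so 1 split, the real one, gave as many. The listed genes had been selected for the real split, so chance cannot be excluded from this count.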
